A study of Mus musculus with 64 samples.

How the data were processed

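RNA was measured in 64 libraries from mouse hearts of the CD1 strain, 4 libraries for each combination of 4 cell populations, 2 ages at surgery and 2 operations, taken 3 days after surgery. Per the labels' protocols, a Ribo-Zero Gold kit removed ribosomal RNA before stranded TruSeq libraries were made, and single-end reads of 50 bases were sequenced on a HiSeq instrument. The submitters' processing notes name Trimmomatic, STAR, HTSeq and edgeR without versions, and the builds mm10, GRCm38 and GRCh38 without roles. Chromatin accessibility data named in the series design were not analysed here.

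The deposited table holds 20637 genes with a normalised signal per library, which the authors named CPM. The column sums differed between libraries, so the authors' values were taken as read counts over effective library sizes. Within each library the deposited signal was a whole multiple of the value of 1 read, 0.0340 to 0.136 CPM, and 100% of the values came out as whole reads within 0.01, giving 9.59 to 27.5 M recovered reads (median 20.6 M). A floor of 3 reads is 0.102 to 0.409 CPM; it covers counting error only, since reads without molecular identifiers are not independent molecules. The authors also deposited a gene length in another unit, bases, used only in checks. The genes' coordinates were taken from the table: 20541 of the IDs are in GENCODE M21 (GRCm38), 20540 of them overlapping the annotated gene, and 96 were not found there. Genes overlapping on the same strand and near-identical copies may share reads, and the strand setting of the counting is not given in the sources used here.

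Groups were taken from the labels. Within groups the 96 pairs of libraries differed by a chi-square per gene of 7.40 to 725 (median 57.6) over recovered reads, and 0 pairs were identical, so each library counted as 1 replicate. The main test was the one planned for normalised values, limma 3.58.1 (R 4.3.3) on log2(value + 0.5), with a mean-variance trend, fitted over the 16 libraries of each population and genes of at least 1 CPM in at least 4 of them (15461 in cardiomyocytes, 15729 in fibroblasts, 16239 in leukocytes and 15706 in endothelial cells). The contrasts were P56 against P1 in sham, MI against sham at each age, and the difference of those 2 changes. Calls needed a Benjamini-Hochberg adjusted p under 0.05 within the contrast. Enrichment was tested over the 32 sham libraries, requiring a log2 difference of at least 1 at an adjusted p under 0.05 against each other population. Adjusted p-values in the report come from limma.

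The gene lists, 33 in number, were fixed before the data were examined: markers of cardiomyocytes, fibroblasts, endothelial cells, leukocytes in general, monocytes and macrophages, neutrophils, T and NK cells, B cells, mural cells, erythroid cells and epicardium; genes of the G2 and M phases, DNA replication, the fetal and stressed heart, calcium handling, fatty acid oxidation, glycolysis, oxidative phosphorylation, mitochondrial coding, the imprinted growth network, extracellular matrix, myofibroblasts, matrix degradation, cytokines and chemokines, interferon response, antigen presentation, resident and injury-associated macrophages, angiogenesis, endothelial leukocyte adhesion, immediate early and heat shock response and hypoxia; and sex-linked genes. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01 (512 tests, adjusted within each contrast), and again with an estimated correlation.

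Named genes followed a rule fixed at the same time. Per contrast it took the 4 largest increases and the 4 largest decreases among called genes with a group mean of at least 5 CPM and no overlap between the groups' replicates (no overlap was asked of the difference between ages), leaving out predicted genes, pseudogenes and clone names. It added from each list of the population up to 3 called members with the smallest adjusted p, or the 2 of highest mean CPM where none was called, and up to 2 from other lists that passed camera. For enrichment it took each marker list and the 4 largest differences. Fewer were printed where possible, from the top of each order.

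Alternatives fixed then were a fold of at least 2, pseudocounts of 0.1 and 1, no filter, a filter at 5 CPM, median-of-ratios scaling, quantile normalization, no variance trend, the replicate number as a block, array weights, fits of only the compared libraries and leaving out each library in turn. After the data were seen, the quasi-likelihood test of edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, leaving out the 7 libraries with over 5% 18S, and leaving out 2 libraries whose exchange called the most genes (P56 cardiomyocyte sham and MI replicates 3, P1 endothelial sham and MI replicates 4) were added. On recovered reads edgeR called 10862, 10764, 10892 and 9906 genes with age in cardiomyocytes, fibroblasts, leukocytes and endothelial cells. After MI at P56 it called 1201, 8139, 9675 and 3318, and at P1 21, 306, 7241 and 27.

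The scripts were tested on counts simulated for MI against sham at P56, with 100 genes changed 2-fold and 100 changed 4-fold. Limma called 38 of the 2-fold and 95 of the 4-fold genes in cardiomyocytes (15118 genes, 12 wrong calls), 75 and 96 in fibroblasts (15440, 9), 70 and 95 in leukocytes (15990, 12) and 85 and 98 in endothelial cells (15503, 6). With no gene changed at P1 it called 0 in each population. In the simulated enrichment of endothelial cells (16608 genes) it recovered 199 of 200 4-fold genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.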

Results

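Total RNA was sequenced from 4 cell populations of the mouse heart, isolated 3 days after a sham operation or after a myocardial infarction (MI) made by permanent ligation of the left anterior descending coronary artery. The surgery was done on postnatal day 1 (P1), an age at which the mouse heart can still rebuild lost muscle, or on postnatal day 56 (P56), when it scars. The populations were a dense cardiomyocyte fraction from a Percoll gradient and 3 populations sorted by surface antigens: fibroblasts (CD90 positive, CD45 and CD31 negative), leukocytes (CD45 positive) and endothelial cells (CD31 positive, CD45 negative). Each of the 16 groups had 4 libraries, 64 in all. Neonatal ventricles were pooled 6 at a time and digested with stirring, while the hearts of adult males were perfused with enzyme, so age was bound up with the isolation and with any difference in sex. The labels do not say that replicate libraries came from separate pools or animals, so p-values measure the spread between these libraries, which may be partly technical.

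The values were normalised read counts in CPM from which whole reads could be recovered. The libraries held 9.59 to 27.5 M recovered reads (M, 1e6; median 20.6 M), so that 3 reads corresponded to 0.102 to 0.409 CPM, a floor for counting error only. Mitochondrial ribosomal RNA took 29.9% ± 6.27 (SD, n = 4) of the reads of P56 sham cardiomyocytes and 21.7% ± 7.12 of those after MI, against 12.1% ± 3.67 and 11.7% ± 3.21 at P1. Nuclear 18S ribosomal RNA exceeded 5% in 7 libraries, among them 1 of 4 P1 sham fibroblast libraries (26.1%) and 2 of 4 P1 MI fibroblast libraries (13.5% and 8.98%). Levels below are mean CPM ± SD (n = 4), and fold changes are log2 values ± standard error on the log2(CPM + 0.5) scale, which understates the change of low genes. Coordinates are on GRCm38.

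The first comparison asked which genes set the populations apart, over the 32 sham libraries with both ages weighted equally. A gene was counted when it was at least 2-fold higher than in each of the other 3 populations. Cardiomyocytes had 2061 such genes, fibroblasts 1245, leukocytes 976 and endothelial cells 882, of 17618 tested. The fibroblast markers were all among them (13 of 13), led by the scavenger receptor gene Scara5, whose lowest log2 difference was 4.95, and the small proteoglycans Lum (4.84) and Dcn (4.82). All 12 pan-leukocyte markers passed, among them Ptprc, which encodes CD45 (5.51), and the largest differences belonged to the inhibitory receptor genes Lilr4b (6.22) and Lilrb4a (5.94) and the mannose receptor Mrc1 (5.64). All 14 endothelial markers passed by smaller margins, with 2.75 for Egfl7, 2.58 for the VEGF receptor Flt1 and 1.13 for the angiopoietin receptor Tek; Vwf, the von Willebrand factor gene, led with 3.21.

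Of the 14 cardiomyocyte markers 12 passed, among them Tnnc1 (3.26), Myl2 (3.32) and Ckm (3.15), and the natriuretic peptide gene Nppb (3.78) and the heart subunits of cytochrome oxidase Cox8b (3.74) and Cox7a1 (3.72) stood among the largest differences with the 5.8S ribosomal RNA gene n-R5-8s1 (4.24). The giant sarcomere gene Ttn (lowest log2 difference -0.68) and the calcium release channel Ryr2 (0.53) did not reach the 2-fold difference. Ttn stood at 75108 ± 41206 CPM in P56 sham leukocytes against 24473 ± 5264 in cardiomyocytes, and Ryr2 at 4526 ± 2715 against 5195 ± 949.9. Myl2 was lower there, 1652 ± 681 against 19732 ± 1464. P1 sham leukocytes held the endothelial transcripts Cdh5 (790.0 ± 54.5 CPM against 1808 ± 195 in endothelial cells) and Cldn5 (503 ± 53.3 against 463 ± 75.7).

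**Figure D1:**
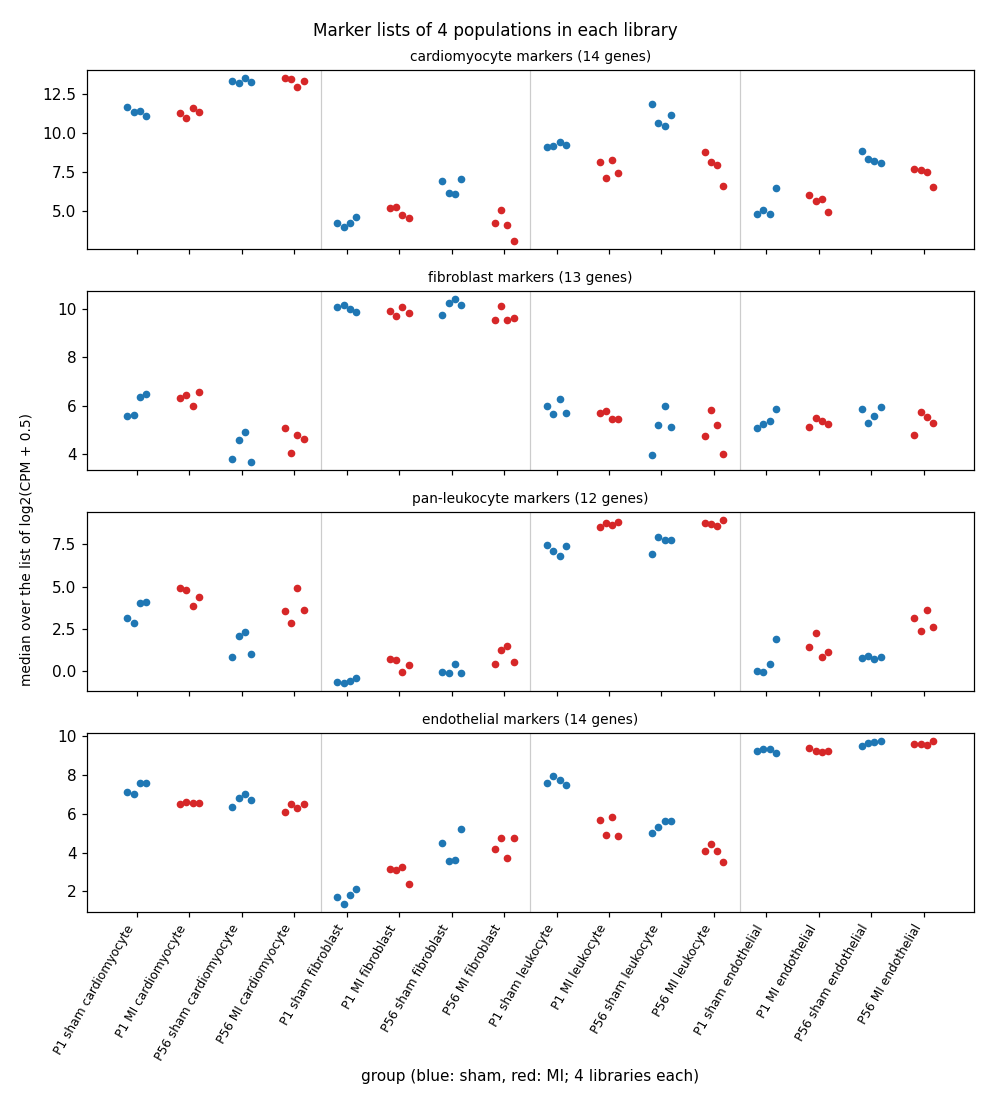
Median level of 4 marker lists in each of the 64 libraries. The vertical axis is the median over the list's genes of log2(CPM + 0.5), the horizontal axis the 16 groups, and each point is 1 library. Cardiomyocyte markers lie higher in P56 sham than in P56 MI leukocytes, and endothelial markers higher in P1 sham than in P1 MI leukocytes.

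The sham libraries of both ages were compared to ask how each population differs between the neonatal and the adult heart. Adult cardiomyocytes had far more RNA of oxidative phosphorylation genes, cardiomyocyte markers and calcium handling and ion channel genes, and far less of cell division genes. Bdh1, which encodes the mitochondrial enzyme that oxidises the ketone body 3-hydroxybutyrate (ENSMUSG00000046598, chromosome 16, 31422280 to 31458901), rose from 0.848 ± 0.308 to 486 ± 77.5 CPM (log2 fold change 8.51 ± 0.21). The sodium channel subunit Scn4b (6.88 ± 0.28), the alpha-skeletal actin gene Acta1 (6.70 ± 0.34) and the carboxylesterase Ces1d (6.44 ± 0.22) followed. Tnni1, the slow skeletal troponin I of the fetal heart (ENSMUSG00000026418, chromosome 1, 135779434 to 135810989), fell from 982 ± 124 to 0.136 ± 0.198 CPM (-10.63 ± 0.21), as did the imprinted noncoding RNA H19 (-7.70 ± 0.35), the DNA topoisomerase Top2a (-7.53 ± 0.43) and Xist (-7.85 ± 0.25), the RNA made from the inactive X chromosome.

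All 25 oxidative phosphorylation genes rose (median 1.99), with Cox7a1 (3.68 ± 0.23) and Cox6a2 (3.17 ± 0.25) foremost, and so did 18 of 20 fatty acid oxidation genes (median 1.67), such as the carnitine transferase Cpt2 (2.55 ± 0.17) and the transcription factor Ppara (2.57 ± 0.23). All 14 cardiomyocyte markers rose (Ckm 3.02 ± 0.33, Tnni3 2.75 ± 0.27, Mb 2.69 ± 0.27). So did all 7 mitochondrially encoded genes tested, 11 of 15 calcium handling and ion channel genes (Hrc 3.43 ± 0.21, Kcnip2 3.91 ± 0.25) and 12 of 17 glycolysis genes, led by the hexokinase Hk2 (3.16 ± 0.14), while 2 fell. Of the hypoxia response genes 8 of 15 rose and 4 fell. All 25 genes of the G2 and M phases fell (median -5.57; Cdk1 -6.68 ± 0.27, Ccnb2 -6.15 ± 0.27), as did all 25 DNA replication genes (median -3.52; Prim1 -5.03 ± 0.21) and all 13 genes of the imprinted growth network (Mest -6.10 ± 0.22, Igf2 -5.77 ± 0.21). So did 20 of 21 extracellular matrix genes (Eln -4.42 ± 0.33), 14 of 15 immediate early and heat shock genes (Egr1 -3.82 ± 0.27) and 19 of 25 cytokine and chemokine genes (Cxcl1 -5.37 ± 0.32).

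Markers of other cells were lower in the adult fraction: 10 of 11 neutrophil markers (Ngp -5.41 ± 0.32), all 6 erythroid markers (Slc4a1 -4.83 ± 0.30), all 7 epicardial markers, 11 of 13 fibroblast markers (Col3a1 -3.83 ± 0.38) and 10 of 14 endothelial markers (Cldn5 -2.63 ± 0.30). Limma called 10877 of 15461 genes at an adjusted p under 0.05, 5149 of them higher at P56 and 5728 lower. Adjusted over the list alone, 19 fatty acid oxidation genes and 1 immediate early gene rose, and the other counts were the same. All the lists named here passed camera with the preset correlation (largest adjusted p 0.0386), and none with an estimated one (adjusted p = 0.148 to 0.347 with an estimated correlation). The fetal and stress genes went both ways (7 up and 4 down of 12, camera adjusted p 0.366), and among the sex-linked genes the median (0.69) and the mean (-0.96) had opposite signs.

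Adult fibroblasts had less RNA for cell division and matrix proteins and more for interferon response and antigen presentation than neonatal ones. The chemokine Cxcl14 (ENSMUSG00000021508, chromosome 13, 56288647 to 56296551) rose from 0.104 ± 0.0261 to 247 ± 46.1 CPM (8.66 ± 0.19), followed by the methyltransferase Inmt (6.85 ± 0.26), the interferon-inducible Ifi205 (6.63 ± 0.35) and Penk (6.42 ± 0.30), the precursor of enkephalin. H19 (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143) fell from 1844 ± 101 to 1.18 ± 0.359 CPM (-10.13 ± 0.30), and Xist (-8.30 ± 0.24), the secreted myofibroblast protein Cthrc1 (-6.89 ± 0.26) and the imprinted Dlk1 (-6.88 ± 0.16) fell after it.

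All 25 G2 and M phase genes (median -4.63; Tpx2 -5.30 ± 0.31, Cdk1 -5.98 ± 0.36), all 25 DNA replication genes (median -2.76; Uhrf1 -5.35 ± 0.29), all 13 imprinted genes and all 15 immediate early genes (Atf3 -5.56 ± 0.27) fell. Of the extracellular matrix genes 16 of 21 fell, the fibronectin gene Fn1 (-3.19 ± 0.22) first, while 3 rose, among them Col8a1 (3.37 ± 0.25). The myofibroblast list split, 7 falling (Acta2 -4.21 ± 0.22) and 3 rising (Cilp 3.53 ± 0.23) of 15, as did the fibroblast markers, 7 falling (Col1a1 -2.37 ± 0.29) and 5 rising (Fbln1 1.77 ± 0.22, Scara5 2.30 ± 0.34) of 13. The matrix-cutting protease Adamts4 (-5.67 ± 0.38) and the cytokine Il6 (-6.03 ± 0.37) fell. Of the interferon-stimulated genes 15 of 17 rose (Ifih1 1.99 ± 0.14, Usp18 2.45 ± 0.20), and of the antigen presentation genes 10 of 13 (Tap2 2.11 ± 0.13). Transcripts of other cells were higher in the adult libraries: 13 of 14 cardiomyocyte markers (Ttn from 98.5 ± 30.0 to 2632 ± 1020 CPM), 12 of 14 endothelial markers (Kdr 2.74 ± 0.29), 9 of 11 monocyte and macrophage markers, 8 of 11 resident macrophage genes (Mrc1 2.60 ± 0.33) and 12 of 15 calcium handling genes. The epicardial markers all fell (7 of 7; Wt1 -2.75 ± 0.26).

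Of 15729 genes limma called 10538, 5481 higher and 5057 lower. When adjusted over the list alone, 17 matrix genes fell, 16 interferon-stimulated genes, 13 calcium handling genes and 14 cardiomyocyte markers rose, and the other counts given were unchanged. Apart from the myofibroblast (0.0728) and fibroblast (0.550) lists, those lists passed camera (largest adjusted p 0.0373). The imprinted list held with an estimated correlation (adjusted p = 0.0303 with an estimated correlation), and the rest did not (adjusted p = 0.431 to 0.713 with an estimated correlation). Median and mean differed in sign for the mural cell markers (0.09 and -0.55, camera direction down), the sex-linked (1.23 and -0.73, up), endothelial adhesion (0.73 and -0.14, up) and matrix degradation genes (0.12 and -0.21, up), none of which passed.

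Adult sham leukocytes had more resident macrophage and antigen presentation RNA, and neonatal ones more neutrophil, cytokine and cell cycle RNA. The genes that rose most were Ces1d (6.38 ± 0.36), the phospholipase Pla2g2d (ENSMUSG00000041202, chromosome 4, 138775735 to 138782046; 6.33 ± 0.29, from 0.0638 ± 0.103 to 45.6 ± 12.0 CPM), Bdh1 (6.21 ± 0.38) and the macrophage lectin Mgl2 (5.90 ± 0.41). The neutrophil granule protein Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767) fell from 403 ± 108 to 0.776 ± 1.13 CPM (-8.60 ± 0.50), with H19 (-8.45 ± 0.21), the endothelial selectin Sele (-8.37 ± 0.25) and Tnni1 (-8.23 ± 0.20). All 12 resident macrophage genes rose (median 2.23; Cbr2 3.77 ± 0.26, Folr2 3.64 ± 0.27, Cd163 3.67 ± 0.34). So did 11 of 14 antigen presentation genes, led by the class II genes H2-Aa (4.71 ± 0.17) and H2-Ab1 (4.69 ± 0.19) and the invariant chain Cd74 (4.58 ± 0.20), and 7 of 12 monocyte and macrophage markers (C1qa 1.79 ± 0.25). All 12 neutrophil markers fell (median -5.71; Ngp -7.51 ± 0.26, Camp -6.39 ± 0.21). 11 of 13 injury-associated macrophage genes (Thbs1 -6.43 ± 0.31, Fabp5 -3.89 ± 0.20) and 19 of 27 cytokine and chemokine genes (Il6 -6.87 ± 0.17, Il1a -6.34 ± 0.31) fell, against 1 and 4 that rose. All 25 DNA replication genes (Rrm2 -3.05 ± 0.14) and 24 of 25 G2 and M phase genes (Foxm1 -2.23 ± 0.13) fell. Among lymphocyte markers, 6 of 13 for T and NK cells rose (Ncr1 3.00 ± 0.36) and 3 fell, and 3 of 10 for B cells rose (Ighm 2.62 ± 0.21) and 2 fell. Interferon-stimulated genes split, 5 rising and 6 falling (Isg15 -1.91 ± 0.31) of 18.

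Along with these, 13 of 14 cardiomyocyte markers (Mb 2.89 ± 0.35, from 373 ± 51.6 to 2882 ± 1080 CPM), all 25 oxidative phosphorylation genes, 18 of 20 fatty acid oxidation genes (Acadm 2.45 ± 0.25) and 12 of 15 calcium handling genes were higher in the adult libraries. All 14 endothelial markers (Cldn5 -5.17 ± 0.23, Cdh5 -3.91 ± 0.20), all 10 endothelial adhesion genes, 14 of 16 angiogenesis genes, 9 of 11 mural cell markers and all 6 erythroid markers were lower. Xist, chosen here after its values were seen, stood at 1.80 CPM in P1 sham replicate 4 and at 248 to 748 in the other P1 sham leukocyte libraries. Limma called 10890 of 16239 genes, 5285 higher and 5605 lower. Adjusted over the list alone the counts were the same but for 14 cardiomyocyte markers and 5 cytokine genes that rose. The T and NK, B cell and interferon lists did not pass camera (adjusted p 0.140 to 0.899), the last with a median of 0.01 and a mean of -0.11, and the glycolysis genes had a median of -0.26 and a mean of 0.05 with 6 up and 5 down. The others passed (largest adjusted p 0.0311), but none held (adjusted p = 0.124 to 0.568 with an estimated correlation).

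Adult endothelial cells also had less RNA for cell division and matrix, and more for antigen presentation and interferon response. The flavin monooxygenase Fmo2 (ENSMUSG00000040170, chromosome 1, 162874317 to 162898726) rose from 5.31 ± 1.66 to 389 ± 35.8 CPM (6.11 ± 0.20) and xanthine dehydrogenase Xdh by 5.69 ± 0.17. The muscle genes Ckmt2 (6.00 ± 0.30) and Xirp2 (5.87 ± 0.39) were also among those that rose most. Xist (-9.18 ± 0.27), the transcription factor Sox11 (-5.76 ± 0.28), the heat shock gene Hspa1a (-5.38 ± 0.69) and H19 (-5.36 ± 0.30) fell most. All 25 G2 and M phase genes (median -4.02; Cdk1 -4.64 ± 0.30) and all 25 DNA replication genes (median -2.13; Uhrf1 -3.97 ± 0.24) fell. So did 11 of 13 imprinted genes (Igf2 -4.51 ± 0.15, from 2313 ± 161 to 102 ± 18.4 CPM), 19 of 21 matrix genes (Eln -2.91 ± 0.18), 8 of 14 matrix degradation genes (Mmp2 -1.86 ± 0.14) and 14 of 15 immediate early and heat shock genes (Atf3 -4.14 ± 0.37). Of the interferon-stimulated genes 14 of 17 rose (Ifih1 1.58 ± 0.12, Ifit3 3.00 ± 0.34), and of the antigen presentation genes 11 of 13 (Psmb9 1.81 ± 0.23). Among angiogenesis genes 5 of 16 fell (Nid2 -2.18 ± 0.17, Apln -2.39 ± 0.21) and 1 rose. Of the leukocyte adhesion genes 7 of 10 fell (Sele -4.14 ± 0.29, Madcam1 -2.42 ± 0.14) and 3 rose. Endothelial markers went both ways, 4 up (Flt1 1.08 ± 0.12, Egfl7 0.90 ± 0.11) and 3 down (Cldn5 -1.93 ± 0.32) of 14, and the chemokine Cxcl12 rose (2.00 ± 0.16) while Cxcl1 fell (-3.33 ± 0.20).

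In the same libraries all 14 cardiomyocyte markers (Mb 4.08 ± 0.33, Pln 3.30 ± 0.29), 13 of 15 calcium handling genes (Hrc 4.73 ± 0.35), 18 of 19 fatty acid oxidation genes, 17 of 25 oxidative phosphorylation genes and 9 of 11 mural cell markers (the pericyte gene Rgs5 2.19 ± 0.15) were higher at P56, and all 6 erythroid markers lower. Limma called 9878 of 15706 genes, 5279 higher and 4599 lower. When adjusted over the list alone, 12 imprinted genes fell and the other counts were the same. The angiogenesis, adhesion and endothelial marker lists did not pass camera (adjusted p 0.0562 to 0.707). The others did (largest adjusted p 0.0219), but not with an estimated correlation (adjusted p = 0.253 to 0.574 with an estimated correlation). Signs of median, mean and test differed for the myofibroblast (0.24, -0.51, down), sex-linked (1.36, -0.76, up), hypoxia (-0.10, 0.16, up) and pan-leukocyte lists (0.03, 0.01, down), none of which passed.

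**Figure D2:**
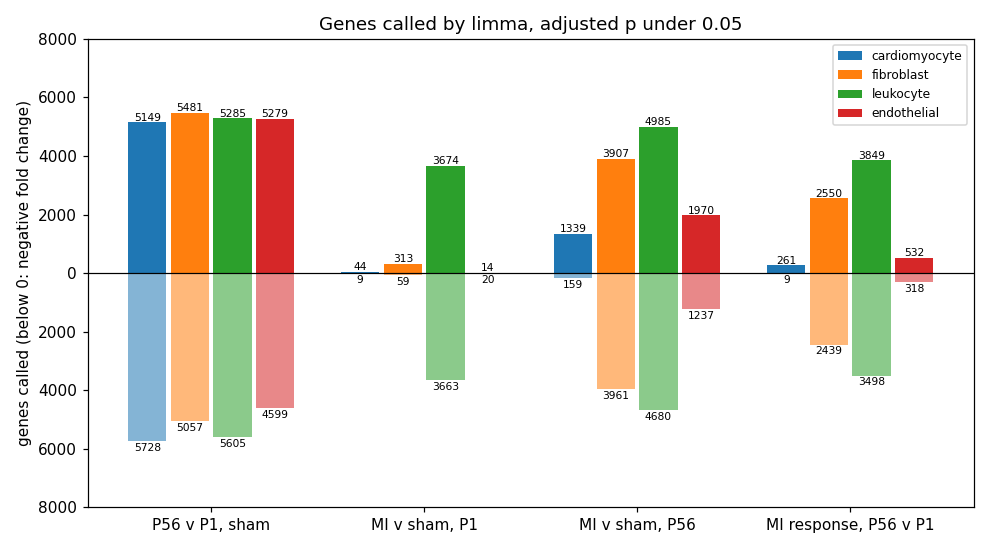
Number of genes called by limma (adjusted p under 0.05) in each population for the 3 group comparisons and the difference between the MI responses. Bars above 0 count positive and bars below 0 negative log2 fold changes, on a linear axis that starts at 0. At P1 MI calls were 53 in cardiomyocytes (2 to 80 without 1 library), 34 in endothelial cells (0 to 261) and 7337 in leukocytes.

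MI and sham libraries were then compared at each age to ask which genes each population changes after injury. In neonatal cardiomyocytes the calls were few and led by genes of activated macrophages. The secreted phosphoprotein gene Spp1, osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose from 75.8 ± 78.0 to 1082 ± 477 CPM (4.79 ± 0.87, adjusted p 0.0227), and the glycoprotein Gpnmb (4.36 ± 0.76), the macrophage elastase Mmp12 (4.25 ± 0.54) and arginase, Arg1 (3.26 ± 0.44), rose with it. The transcription factor Tcf15 (-1.34 ± 0.28), Sez6l2 (-1.21 ± 0.23) and the potassium channel Kcna5 (-1.08 ± 0.23) fell. Of the injury-associated macrophage genes 5 of 13 rose, 6 adjusted over the list alone, and 2 of 25 cytokine and chemokine genes rose (Il1a 1.81 ± 0.28, Il1rn 2.61 ± 0.48), or 11 adjusted over the list alone with 1 that fell. Monocyte and macrophage markers had 1 of 12 called (Mpeg1 2.11 ± 0.42) and 7 adjusted over the list alone. Of the endothelial markers 2 of 14 fell over all genes (Cdh5 -0.87 ± 0.15, Tie1 -0.98 ± 0.21), and 9 adjusted over the list alone. All 4 lists passed camera (largest adjusted p 7.72e-10), but none held (adjusted p = 0.244 to 0.312 with an estimated correlation). The matrix degradation genes passed upward (0.0485; 0.803 as adjusted p with an estimated correlation) with a median of -0.07 and a mean of 0.44, 1 of 15 being called. The G2 and M phase and the cardiomyocyte marker lists had no called member.

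Limma called 53 genes, 44 higher and 9 lower. That count depended on single libraries: 20 without sham replicate 1, 80 without sham replicate 2, 30 without sham replicate 3, and 2, 9 and 3 without MI replicates 1, 2 and 4. Among tools chosen after the data were seen edgeR called 21 and DESeq2 301, and leaving out the libraries over 5% 18S gave 129, 58 higher and 71 lower.

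In adult cardiomyocyte libraries matrix, leukocyte and cell cycle transcripts rose after MI. Spp1 rose from 0.160 ± 0.187 to 241 ± 304 CPM (7.82 ± 0.87), the matrix glycoprotein Tnc from 1.34 ± 0.444 to 162 ± 80.6 (6.28 ± 0.42), and Arg1 (6.63 ± 0.44) and the acute phase gene Saa3 (6.03 ± 0.76) rose too. The potassium channel subunit Kcnv2 (-1.91 ± 0.40), the myosin light chain kinase Mylk4 (-1.74 ± 0.36), the secreted Lgi1 (-2.01 ± 0.30) and the mitochondrial tRNA mt-Ti (-1.60 ± 0.29) fell. Of the fetal and stress genes of the heart 7 of 12 rose, including the natriuretic peptides Nppa (2.37 ± 0.46, from 292 ± 162 to 1581 ± 1030 CPM) and Nppb (2.07 ± 0.48) and the stress cytokine Gdf15 (1.20 ± 0.29). Matrix genes rose, 16 of 21 (Lox 4.17 ± 0.36, Col12a1 4.25 ± 0.40, Fn1 3.27 ± 0.31), with 10 of 15 myofibroblast genes (Timp1 5.30 ± 0.42) and 9 of 15 matrix degradation genes (Adamts4 3.55 ± 0.40). 20 of 25 G2 and M phase genes (median 1.78; Ccnb2 2.57 ± 0.27, Cdk1 from 0.933 ± 0.263 to 7.65 ± 3.70 CPM) and 17 of 25 DNA replication genes (Cdc6 1.95 ± 0.23, Mcm3 1.49 ± 0.20) rose. The calcium-binding gene Hrc (-0.77 ± 0.21) was the 1 called member of the 15 calcium handling genes, glucose transporter Slc2a1 (1.18 ± 0.28) and Pfkp (0.79 ± 0.23) the 2 of 17 glycolysis genes. No cardiomyocyte marker and no gene of fatty acid oxidation (median -0.15) or oxidative phosphorylation (median -0.13) was called, although both metabolic lists passed camera downward (adjusted p = 0.346 to 0.556 with an estimated correlation).

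All 12 pan-leukocyte markers rose (Cd52 2.33 ± 0.31, Rac2 2.16 ± 0.29), with 12 of 13 injury-associated macrophage genes, 7 of 12 monocyte and macrophage markers (Itgam 3.55 ± 0.42), 17 of 25 cytokine genes (Ccl2 3.42 ± 0.42), 4 of 11 neutrophil markers (Lcn2 4.46 ± 0.60), 4 of 13 fibroblast markers (Col1a1 3.77 ± 0.50) and 4 of 7 epicardial markers. Of the endothelial markers 1 of 14 fell (Kdr -0.91 ± 0.25). Adjusted over the list alone, 23 G2 and M phase, 20 replication, 18 matrix, 11 degradation, 11 macrophage, 18 cytokine, 5 neutrophil, 5 fibroblast, 6 epicardial and 4 glycolysis genes rose, 1 fibroblast marker fell, and the other counts given were the same. Apart from glycolysis (0.0706) these lists passed camera (largest adjusted p 0.0292) and none with an estimated correlation (adjusted p = 0.133 to 0.556 with an estimated correlation). Interferon-stimulated (median 0.04, mean 0.07) and angiogenesis genes (0.09, 0.18) had positive centres and a downward test, neither passing.

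Limma called 1498 genes, 1339 higher and 159 lower. Mitochondrial ribosomal RNA took 12.1% of MI replicate 3 (20.3 to 27.3% in the others) and 38.2% of sham replicate 3 (23.1 to 29.9%), neither being past the limit of Dixon's test. Without MI replicate 3 the count was 3679, and without sham replicate 1 or MI replicates 1 and 4 it was 998, 896 and 957.

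In neonatal fibroblast libraries epicardial, myofibroblast and macrophage transcripts rose after MI. Spp1 rose from 1.37 ± 0.788 to 24.3 ± 14.4 CPM (3.63 ± 0.53), lysozyme Lyz2 by 2.40 ± 0.41, the CCN family gene Wisp2 by 2.20 ± 0.24 and the laminin chain Lamc3 by 2.16 ± 0.27. The ion exchanger Slc24a2 (-1.43 ± 0.13), the prolactin receptor Prlr (-1.26 ± 0.20), Milr1 (-1.24 ± 0.21) and Zfp711 (-1.17 ± 0.26) fell. Of the epicardial markers 6 of 7 rose (Lrrn4 1.92 ± 0.32, Krt19 1.51 ± 0.27), and 7 adjusted over the list alone. Of the myofibroblast genes 5 of 15 rose (the TGF-beta binding Ltbp2 1.67 ± 0.25, Cilp 1.54 ± 0.23, Tagln 1.11 ± 0.19), or 9 with 1 lower over the list alone. Matrix genes had 2 of 21 called (Col8a1 1.22 ± 0.25, Col12a1 1.09 ± 0.27), 3 over the list alone, and the imprinted Dlk1 fell (-1.01 ± 0.16), 1 of 13 in its list. The interferon-stimulated Oasl2 rose (1.02 ± 0.20), 1 of 17 and 2 over the list alone, and of the cytokine genes 2 of 17 rose (Lif 1.08 ± 0.25), 7 over the list alone. No fibroblast marker, matrix degradation gene or gene of the G2 and M phases or DNA replication was called, though the fibroblast list passed camera downward (median -0.30; adjusted p = 0.336 with an estimated correlation).

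Among transcripts of other cells, 3 of 11 macrophage markers rose and 1 fell (10 and 1 adjusted over the list alone). 2 of 8 pan-leukocyte markers (7 over the list alone), 3 of 14 endothelial markers (9 over the list alone) and 4 of 12 fetal and stress genes (Myl7 1.85 ± 0.31; 8 over the list alone) rose. All of these but the interferon list (0.356) passed camera (largest adjusted p 0.00916), but none held (adjusted p = 0.117 to 0.487 with an estimated correlation). Limma called 372 genes, 313 higher and 59 lower. Without the libraries over 5% 18S, an alternative chosen after the data were seen, it was 644 with 174 higher and 470 lower, so most of the calls then pointed down. The count was 159, 219 and 241 without sham replicates 2, 3 and 4, and 155 and 246 without MI replicates 1 and 4.

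In adult fibroblasts cell division, myofibroblast and matrix genes rose after MI. Spp1 rose from 0.250 ± 0.259 to 255 ± 179 CPM (8.13 ± 0.53), Cthrc1 from 0.189 ± 0.222 to 122 ± 60.5 (7.39 ± 0.26), Tnc by 6.87 ± 0.34 and the CCN family gene Wisp1 by 6.44 ± 0.28. The carboxylesterase Ces1d (-2.98 ± 0.36), the B cell adaptor Blnk (-2.80 ± 0.22), Lrtm1 (-2.87 ± 0.29) and the myosin gene Myh6 (-2.90 ± 0.35) fell most. Of the myofibroblast genes 14 of 15 rose (median 2.93), with smooth muscle actin Acta2 at 12.9 ± 2.46 CPM after sham and 443 ± 155 after MI (4.99 ± 0.22) and Tagln (4.08 ± 0.19). All 25 G2 and M phase genes (median 4.14; Tpx2 4.71 ± 0.31, Cdk1 5.09 ± 0.36) and all 25 DNA replication genes (median 2.30; Uhrf1 4.68 ± 0.29, Mcm5 3.83 ± 0.25) rose. So did 16 of 21 matrix genes (Col12a1 4.68 ± 0.27, the crosslinking enzyme Lox 3.33 ± 0.23), 14 of 17 cytokine and chemokine genes (Il6 5.99 ± 0.37, Ccl9 4.88 ± 0.36, Cxcl5 4.44 ± 0.42), 11 of 16 glycolysis genes (Ldha 1.59 ± 0.13) and 11 of 15 immediate early genes (Atf3 2.73 ± 0.27). Matrix degradation genes split, 8 up (Adamts4 3.55 ± 0.38) and 5 down (Adamts5 -1.39 ± 0.18) of 13, as did fibroblast markers, 4 up (Col1a1 2.36 ± 0.29, Mfap5 1.13 ± 0.17) and 5 down (Dcn -1.22 ± 0.21) of 13. The fetal imprinted RNA H19 rose (4.54 ± 0.30) and the cell cycle inhibitor Cdkn1c fell (-1.17 ± 0.21), 3 up and 1 down of 13 in that list, and of the interferon-stimulated genes 3 rose (Isg15 1.01 ± 0.26) and 1 fell of 17.

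At the same time all 14 cardiomyocyte markers fell (Mb -2.70 ± 0.27, Myl2 -2.66 ± 0.27), with 11 of 15 calcium handling and 12 of 18 fatty acid oxidation genes (Fabp3 -2.07 ± 0.24), and 4 of 8 pan-leukocyte markers, 8 of 10 injury-associated macrophage genes and all 7 epicardial markers rose. Limma called 7868 genes, 3907 higher and 3961 lower. With p adjusted over the list alone, 15 cytokine genes and 5 fibroblast markers rose and the other counts were the same. The matrix degradation, fibroblast, imprinted and interferon lists did not pass camera (adjusted p 0.336 to 0.792), and the others did (largest adjusted p 0.0483) but not with an estimated correlation (adjusted p = 0.192 to 0.672 with an estimated correlation). Signs differed between median and mean for the fibroblast markers (-0.31, 0.03, test down) and oxidative phosphorylation (0.14, -0.04, test up), and endothelial markers (0.06, 0.01) had a downward test, none passing.

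Neonatal leukocytes gained macrophage RNA after MI. Arg1 (ENSMUSG00000019987, chromosome 10, 24915208 to 24927470) rose from 45.7 ± 25.1 to 468 ± 229 CPM (3.39 ± 0.37), followed by the collagen Col6a5 (3.23 ± 0.41), the resistin-like Retnla (3.20 ± 0.82) and complement C4b (2.94 ± 0.43). The cytochrome Cyp1a1 (-5.00 ± 0.18), the tight junction gene Cldn5 (-4.21 ± 0.23, from 503 ± 53.3 to 27.1 ± 5.03 CPM), the activin subunit Inhbb (-4.00 ± 0.26) and stanniocalcin Stc1 (-3.71 ± 0.27) fell. All 12 monocyte and macrophage markers rose (Mpeg1 1.87 ± 0.19, Lyz2 2.25 ± 0.23), as did all 12 resident macrophage genes (Timd4 2.57 ± 0.31, Folr2 1.77 ± 0.27). So did 10 of 13 injury-associated genes (Ccr2 2.23 ± 0.22), 9 of 14 antigen presentation genes (H2-Ab1 1.17 ± 0.19), 8 of 10 B cell markers (Cd37 1.43 ± 0.20) and all 12 pan-leukocyte markers. Neutrophil markers had 1 of 12 called (Csf3r 0.99 ± 0.28) and T and NK cell markers 3 of 13 (Nkg7 1.04 ± 0.30). Cytokine genes split, 6 up (Ccl6 2.39 ± 0.36) and 5 down (Cxcl12 -2.19 ± 0.27) of 27, as did interferon-stimulated genes, 2 up (Zbp1 1.66 ± 0.33) and 5 down (Ifi44 -2.23 ± 0.33) of 18. No G2 and M phase gene was called, and 2 DNA replication genes rose and 1 fell (Cdc45 -0.49 ± 0.13).

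All 14 endothelial markers (Erg -2.96 ± 0.18), all 10 endothelial adhesion genes, 14 of 16 angiogenesis genes (Robo4 -3.08 ± 0.24), 8 of 11 mural cell markers, all 6 erythroid markers, 13 of 14 cardiomyocyte markers (Tnni3 -1.60 ± 0.34) and 12 of 13 imprinted genes (Mest -2.45 ± 0.19) were lower after MI. Limma called 7337 genes, 3674 higher and 3663 lower. Adjusted over the list alone, 9 B cell and 1 angiogenesis genes rose, 9 mural markers fell and no replication gene rose, with the other counts the same. The neutrophil, T and NK, cytokine, interferon and replication lists did not pass camera (adjusted p 0.176 to 0.872), the interferon list with a median of 0.08 and a mean of -0.10, and matrix degradation genes differed likewise (0.04 and -0.30). The others passed (largest adjusted p 0.00151), but none held (adjusted p = 0.0912 to 0.630 with an estimated correlation).

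In adult leukocytes injury-associated macrophage, neutrophil and cell cycle genes rose after MI. Spp1 rose from 9.60 ± 5.50 to 4728 ± 1550 CPM (8.97 ± 0.54), Arg1 from 1.36 ± 0.236 to 888 ± 277 (8.85 ± 0.37), and Saa3 (7.93 ± 0.31) and the chitinase-like Chil3 (6.82 ± 0.58) rose next. Spp1 was lower in the other adult MI populations, where its carry-over from leukocytes was not tested. All 13 injury-associated macrophage genes rose (median 4.57; Fn1 6.02 ± 0.25, the lipid carrier Fabp5 4.57 ± 0.20). Monocyte and macrophage markers went both ways, 6 up (Itgam 2.11 ± 0.23) and 5 down of 12, 6 of 12 resident macrophage genes fell (Timd4 -1.69 ± 0.31, Igf1 -1.14 ± 0.24), and so did 3 of 14 antigen presentation genes (H2-Aa -1.16 ± 0.17, Cd74 -1.03 ± 0.20). 8 of 12 neutrophil markers rose (Mmp8 4.21 ± 0.35, the chemokine receptor Cxcr2 4.54 ± 0.52), as did 21 of 27 cytokine and chemokine genes (Il6 3.79 ± 0.17, Cxcl5 4.44 ± 0.36), while 2 fell. All 25 replication (Rrm2 2.74 ± 0.14) and 24 of 25 G2 and M phase genes (Foxm1 1.91 ± 0.13, Bub1 2.42 ± 0.19) rose. Of the T and NK cell markers 7 of 13 fell (Ncr1 -1.70 ± 0.36) and 1 rose (Il7r 2.22 ± 0.40), of the B cell markers 3 rose and 3 fell (Ighm -1.26 ± 0.21), and 5 of 18 interferon-stimulated genes rose (Isg15 1.38 ± 0.31). Matrix genes rose, 18 of 21 (Thbs1 6.22 ± 0.31), with 8 of 15 myofibroblast genes (Timp1 5.67 ± 0.27).

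The largest decreases were those of Mylk4 (-4.17 ± 0.44), Lrtm1 (-4.13 ± 0.47), the muscle gene Cmya5 (-4.03 ± 0.37) and Hrc (-3.89 ± 0.39). All 14 cardiomyocyte markers fell (Mb from 2882 ± 1080 to 274 ± 137 CPM), with all 25 oxidative phosphorylation, all 20 fatty acid oxidation and all 7 mitochondrially encoded genes tested, 14 of 15 calcium handling genes and 13 of 14 endothelial markers, and all 12 pan-leukocyte markers rose. Limma called 9665 genes, 4985 higher and 4680 lower. With p adjusted over the list alone, 7 macrophage markers and 3 interferon-stimulated genes rose, 5 resident macrophage and 15 calcium handling genes fell, and the other counts were the same. The monocyte, resident, antigen presentation, T and NK, B cell and interferon lists did not pass camera (adjusted p 0.0559 to 0.929). The rest did (largest adjusted p 0.00974), but not with an estimated correlation (adjusted p = 0.158 to 0.551 with an estimated correlation).

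In neonatal endothelial cells few genes passed the test after MI. The lipoprotein receptor gene Lrp3 (ENSMUSG00000001802, chromosome 7, 35200027 to 35215370) rose from 2.48 ± 0.586 to 6.47 ± 0.653 CPM (1.24 ± 0.22, adjusted p 0.0342), with the growth factor Pdgfa (1.01 ± 0.17), the cadherin Fat1 (0.97 ± 0.19) and the NF-kB inhibitor Tnfaip3 (0.91 ± 0.13). Nlrp6 (-1.59 ± 0.23), Coro6 (-0.96 ± 0.17), Zfp949 (-0.85 ± 0.15) and the class I gene H2-Q4 (-0.83 ± 0.14) fell. No member of any list tested was called over all genes. Adjusted over the list alone, 14 of 21 matrix, 8 of 11 injury-associated macrophage, 7 of 11 mural, 7 of 20 cytokine and 5 of 10 adhesion genes rose and 3 of 17 interferon-stimulated genes fell. These lists passed camera (medians 0.62, 0.93, 0.49, 0.50, 0.47 and -0.52, largest adjusted p 0.0244), but none held (adjusted p = 0.268 to 0.440 with an estimated correlation). Limma called 34 genes, 14 higher and 20 lower, of which 8 changed at least 2-fold. The count was 8, 1, 2 and 261 without sham replicates 1, 2, 3 and 4 and 0, 0 and 109 without MI replicates 1, 2 and 4, with 2222 genes at an unadjusted p under 0.05 in the full set; edgeR called 27 and DESeq2 334.

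Adult endothelial libraries held more cell cycle, matrix and adhesion molecule RNA after MI. Spp1 rose from 0.142 ± 0.162 to 124 ± 93.7 CPM (7.34 ± 0.76), with Tnc (4.43 ± 0.37), the protease inhibitor Timp1 (4.25 ± 0.26) and Sh2d5 (4.23 ± 0.39). Leukocyte RNA in these libraries, whose markers also rose, was not separated from the rise of Spp1. Mylk4 (-2.09 ± 0.24), Lrtm1 (-1.90 ± 0.32), the GTPase Tgtp2 (-1.87 ± 0.41) and Hrc (-1.63 ± 0.35) fell. All 25 G2 and M phase genes (median 2.03; Plk1 1.77 ± 0.21, Cdk1 from 3.24 ± 2.10 to 17.9 ± 7.38 CPM) and 23 of 25 replication genes (Uhrf1 2.29 ± 0.24) rose. Of the leukocyte adhesion genes 5 of 10 rose, the venule receptor Ackr1 (2.23 ± 0.18) and the selectins Selp (3.14 ± 0.29) and Sele (2.26 ± 0.29) first. 13 of 21 matrix genes (Lox 2.14 ± 0.22, Thbs1 2.61 ± 0.36), 11 of 15 myofibroblast genes and 13 of 20 cytokine genes (Ccl6 3.27 ± 0.32, Ccl9 3.06 ± 0.35) rose. Angiogenesis genes had 3 up (Plvap 1.76 ± 0.28, Apln 1.05 ± 0.21, Pgf 1.35 ± 0.28) and 1 down of 16, endothelial markers 2 up (Sox17 0.38 ± 0.12) and 1 down (Kdr -0.61 ± 0.15) of 14. Of the imprinted genes 4 of 13 rose (Igf2 0.86 ± 0.15, H19 1.49 ± 0.30) and 1 fell. Interferon-stimulated (2 of 17; Rsad2 -1.21 ± 0.33) and antigen presentation genes (2 of 13; H2-D1 -0.62 ± 0.20) had only decreases among the called members.

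Alongside, 9 of 10 pan-leukocyte markers (Lcp1 1.82 ± 0.25), 7 of 12 macrophage markers (Cd14 2.02 ± 0.21) and 9 of 11 injury-associated macrophage genes rose. By contrast, 8 of 14 cardiomyocyte (Pln -1.33 ± 0.29), 6 of 11 mural (Abcc9 -1.24 ± 0.12, Rgs5 -1.26 ± 0.15), 14 of 25 oxidative phosphorylation and 15 of 19 fatty acid oxidation genes fell, while 2 mural markers rose. Limma called 3207 genes, 1970 higher and 1237 lower. When adjusted over the list alone, 25 replication, 6 adhesion, 14 matrix, 12 myofibroblast, 15 cytokine, 10 leukocyte, 9 macrophage, 5 imprinted and 3 mural genes rose and 13 cardiomyocyte, 17 oxidative phosphorylation, 17 fatty acid oxidation, 4 antigen presentation and 2 myofibroblast genes fell, the other counts being the same. The antigen presentation, imprinted, angiogenesis and endothelial lists did not pass camera (adjusted p 0.0974 to 0.612), and the signs of median and mean differed for endothelial (0.02, -0.02, test down) and fibroblast markers (-0.18, 0.19, test up) and hypoxia genes (-0.03, 0.12, test up). The others passed (largest adjusted p 0.0118), but not with an estimated correlation (adjusted p = 0.203 to 0.543 with an estimated correlation).

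The last comparison tested whether the change after MI differed between the ages, as the P56 change minus the P1 change. In cardiomyocytes the difference was positive for Tnc (5.93 ± 0.59), which went from 109 ± 50.6 to 134 ± 51.5 CPM at P1 and from 1.34 ± 0.444 to 162 ± 80.6 at P56, for Lcn2 (4.91 ± 0.85), Saa3 (4.67 ± 1.07) and Timp1 (4.11 ± 0.59). It was negative for Mylk4 (-2.42 ± 0.51), Lgi1 (-1.94 ± 0.42), Cmya5 (-1.79 ± 0.37) and the amylase Amy1 (-1.78 ± 0.43). It was positive for 15 of 25 G2 and M phase genes (21 adjusted over the list alone; Ccnb2 2.84 ± 0.38), 12 of 25 replication genes (20 over the list alone; Mcm3 1.84 ± 0.28) and 10 of 21 matrix genes (20 over the list alone; Col12a1 3.79 ± 0.57), and for 2 of 13 imprinted genes (3 over the list alone; Mest 1.54 ± 0.31). Pan-leukocyte markers had 1 of 12 called, 9 over the list alone. All but the imprinted list (0.0919) passed camera (largest adjusted p 1.83e-05), but none held (adjusted p = 0.1996 to 0.413 with an estimated correlation). Limma called 270 genes, 261 positive and 9 negative. The count was 424, 126 and 155 without P1 sham replicates 2, 3 and 4, 179, 147 and 142 without P1 MI replicates 1, 3 and 4, 179 without P56 sham replicate 1, and 154, 685, 2298 and 168 without P56 MI replicates 1, 2, 3 and 4; edgeR called 331 and DESeq2 639.

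Fibroblasts had 4989 genes whose response differed, 2550 positive and 2439 negative. Cthrc1 (7.10 ± 0.36) stood at 78.5 ± 7.15 and 96.4 ± 6.51 CPM in neonatal sham and MI libraries and at 0.189 ± 0.222 and 122 ± 60.5 in adult ones, and the proliferation gene Mki67 (6.10 ± 0.77), Tnc (6.01 ± 0.49) and Top2a (5.85 ± 0.70) followed. All 25 G2 and M phase (median 4.30) and all 25 replication genes (median 2.31) had a positive difference, with 9 of 15 myofibroblast (12 adjusted over the list alone; Acta2 4.34 ± 0.31), 12 of 21 matrix and 7 of 17 cytokine genes (10 over the list alone; Il6 5.72 ± 0.53). All 14 cardiomyocyte markers had a negative one (Mb -3.41 ± 0.38; Myh6 -3.69 ± 0.49, Ttn -3.59 ± 0.54), as did 5 of 14 endothelial markers (Kdr -2.13 ± 0.41; 6 over the list alone). These lists passed camera (largest adjusted p 0.0164), but none held (adjusted p = 0.225 to 0.683 with an estimated correlation). Signs differed for mural (-0.09, 0.52, up), oxidative phosphorylation (0.06, -0.15, up), resident macrophage (-0.48, 0.02, down) and interferon lists (0.08, 0.02, down), none passing.

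Leukocytes had 7347, 3849 positive and 3498 negative. Tnc (6.89 ± 0.50), Spp1 (6.41 ± 0.76), Thbs1 (6.00 ± 0.45) and the prostaglandin synthase Ptgs2 (5.85 ± 0.78) had the largest positive differences. Spp1 was already at 1476 ± 1080 CPM in neonatal sham leukocytes and at 7474 ± 3470 after MI. Negative ones were Retnla (-5.59 ± 1.16), Timd4 (-4.26 ± 0.43), Bdh1 (-3.91 ± 0.53) and the scavenger receptor Cd163l1 (-3.87 ± 0.56); Timd4 went from 5.31 ± 2.11 to 34.6 ± 14.4 CPM at P1 and from 50.6 ± 15.6 to 15.1 ± 3.98 at P56. The difference was negative for 11 of 12 resident macrophage genes (Folr2 -2.73 ± 0.39), 7 of 12 macrophage markers (Csf1r -1.68 ± 0.28), 6 of 14 antigen presentation genes (H2-Aa -2.15 ± 0.24), 7 of 13 T and NK and 4 of 10 B cell markers. It was positive for 11 of 13 injury-associated (Fabp5 3.95 ± 0.29), 7 of 12 neutrophil (Mmp8 4.17 ± 0.50), 24 of 25 G2 and M phase, 24 of 25 replication and 14 of 27 cytokine genes (Il6 5.42 ± 0.24). RNA of other cells was not separated: 12 of 14 cardiomyocyte markers were negative and 13 of 14 endothelial ones positive. With p adjusted over the list alone, 25 replication, 13 cardiomyocyte and 14 endothelial genes differed, and the other counts were the same. All passed camera (largest adjusted p 0.0137), but none held (adjusted p = 0.246 to 0.415 with an estimated correlation).

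Endothelial cells had 850, 532 positive and 318 negative. Spp1 (4.43 ± 1.07), Sh2d5 (3.70 ± 0.55), Tnc (3.60 ± 0.52) and Timp1 (3.58 ± 0.37) led the positive and the dipeptidase Dpep1 (-2.27 ± 0.60), Mylk4 (-2.25 ± 0.34), Ckm (-2.25 ± 0.51) and Clstn2 (-2.21 ± 0.55) the negative differences. Timp1 went from 2.82 ± 0.204 to 4.92 ± 1.54 CPM at P1 and from 0.438 ± 0.124 to 18.5 ± 6.98 at P56. It was positive for 23 of 25 G2 and M phase genes (25 adjusted over the list alone; Bub1 2.36 ± 0.43), 12 of 25 replication genes (20 over the list alone; Uhrf1 2.12 ± 0.35) and 2 of 10 adhesion genes (4 over the list alone; Ackr1 1.51 ± 0.25, Selp 2.17 ± 0.41). It was negative for 6 of 11 mural (7, and 1 positive, over the list alone; Abcc9 -1.50 ± 0.18) and 7 of 14 cardiomyocyte markers (11 over the list alone). These passed camera (largest adjusted p 0.0148), but none held (adjusted p = 0.301 to 0.382 with an estimated correlation). The count was 489 and 452 without P1 sham replicates 2 and 3, 543 and 511 without P1 MI replicates 1 and 3, 538 without P56 sham replicate 3 and 1712 without P56 MI replicate 2; DESeq2 called 1392.

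The genes called after MI at both ages in the same direction were counted beside the number that independent lists of those sizes would share. They were 27 up (3.81 for independent lists) and 2 down (0.0926) in cardiomyocytes, 138 (77.7) and 17 (14.9) in fibroblasts, 1849 (1128) and 1706 (1056) in leukocytes, and 5 (1.76) and 4 (1.58) in endothelial cells. The comparisons at the 2 ages share no library. In leukocytes 452 genes rose at P1 and fell at P56 and 598 fell and then rose, in fibroblasts 42 and 4, and in endothelial cells 1 fell and then rose. Leaving out 1 library moved no leukocyte count over 1.5 times. The libraries left out below are of P1 unless stated. In cardiomyocytes the 27 became 7, 2, 6 and 3 without sham replicate 1 and MI replicates 1, 2 and 4. The 2 became 1 without sham replicate 1, 4 without sham replicate 2 or P56 sham replicate 1, and 0 without sham replicate 3 or 4 or any single MI library. In fibroblasts the 138 became 86, 69, 68 and 89 without sham replicates 1 and 2 and MI replicates 1 and 4, and the 17 became 5, 8 and 10 without sham replicates 2 and 3 and MI replicate 1. The 42 became 18, 15, 19 and 21 without sham replicates 1, 2, 3 and 4 and 10 and 22 without MI replicates 1 and 3. The 4 became 2 without sham replicate 2 or 4 or MI replicate 3, 1 without MI replicate 4 and 0 without sham replicate 3 or MI replicate 1. In endothelial cells the 5 and 4 were 0 without sham replicate 1, 2 or 3 or MI replicate 1 or 2. They were 62 and 18 without sham replicate 4, 9 and 5 without MI replicate 3, and 10 and 8 without MI replicate 4. The 1 became 2 without sham replicate 4 and 0 without sham replicate 2 or 3 or MI replicate 1, 2 or 3.

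**Figure D3:**
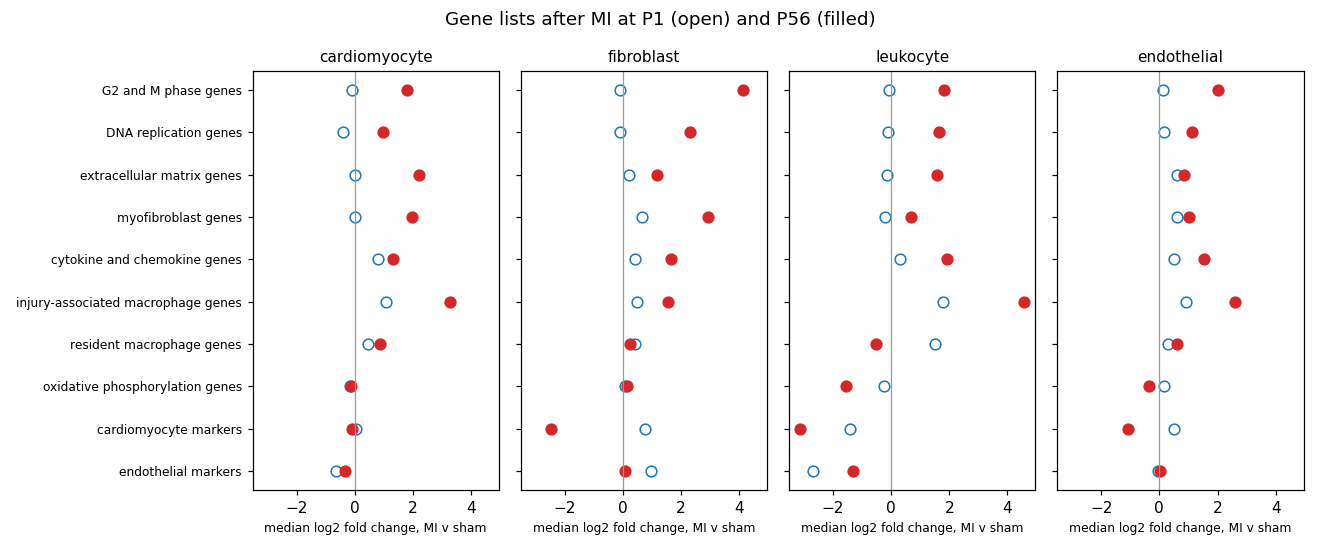
Median log2 fold change after MI of 10 gene lists in each population, at P1 (open circles) and P56 (filled circles). The horizontal axis is the median over the list's tested genes. The G2 and M phase list lies at 4.14 in P56 fibroblasts, and the injury-associated macrophage list at 4.57 in P56 and 1.80 in P1 leukocytes.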

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

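The tests of explanations below were chosen only after the results they address had been seen, and the counts over other splits of the libraries were planned beforehand. The change after MI differed between the ages, by the tested difference of the 2 changes in limma, in 270 genes of cardiomyocytes, 4989 of fibroblasts, 7347 of leukocytes and 850 of endothelial cells. Among the named genes the log2 difference, P56 minus P1, was in cardiomyocytes Tnc 5.93, Lcn2 4.91, Saa3 4.67, Timp1 4.11, Col12a1 3.79, Ccnb2 2.84, Mcm3 1.84 and Mest 1.54, and Mylk4 -2.42, Lgi1 -1.94, Cmya5 -1.79 and Amy1 -1.78. In fibroblasts it was Cthrc1 7.10, Mki67 6.10, Tnc 6.01, Top2a 5.85, Il6 5.72 and Acta2 4.34, and Myh6 -3.69, Ttn -3.59, Mb -3.41 and Kdr -2.13. In leukocytes it was Tnc 6.89, Spp1 6.41, Thbs1 6.00, Ptgs2 5.85, Il6 5.42, Mmp8 4.17 and Fabp5 3.95, and Retnla -5.59, Timd4 -4.26, Bdh1 -3.91, Cd163l1 -3.87, Folr2 -2.73, H2-Aa -2.15 and Csf1r -1.68. In endothelial cells it was Spp1 4.43, Sh2d5 3.70, Tnc 3.60, Timp1 3.58, Bub1 2.36, Selp 2.17, Uhrf1 2.12 and Ackr1 1.51, and Dpep1 -2.27, Mylk4 -2.25, Ckm -2.25, Clstn2 -2.21 and Abcc9 -1.50.

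In 16 of 115 groups of 4 libraries, 1 library lay far from the other 3 by Dixon's test, which by chance picks about 1 in 20 groups. By share of 18S ribosomal RNA these were P1 sham cardiomyocyte replicate 2 (16.6%, the others up to 0.0604%), P1 sham fibroblast replicate 4 (26.1%, up to 0.0199%), P1 sham leukocyte replicate 4 (17.8%, up to 0.228%). The same held for P1 sham endothelial replicate 3 (0.468%, up to 0.0682%), P56 sham leukocyte replicate 3 (0.377%, up to 0.0325%), P1 MI cardiomyocyte replicate 4 (3.78%, up to 0.213%), P56 MI fibroblast replicate 1 (0.125%, up to 0.0412%), P56 MI leukocyte replicate 1 (7.07%, up to 0.190%) and P56 MI endothelial replicate 1 (4.56%, up to 0.0990%). Recovered reads were 15.0 M in P1 sham cardiomyocyte replicate 2 against 25.5 to 26.3 M, and 9.80 M in P1 sham fibroblast replicate 4 against 24.97 to 27.5 M. Among printed gene levels, Spp1 was 694 CPM in P56 MI cardiomyocyte replicate 3 (others 53.0 to 111) and 0.382 in P56 sham endothelial replicate 2 (0.0427 to 0.101). Cdk1 was 6.36 in that same endothelial library (1.79 to 2.51), H19 1995 in P1 sham fibroblast replicate 2 (1781 to 1806) and Ltf 2.46 in P56 sham leukocyte replicate 4 (0.0886 to 0.393).

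The genes that fell after MI in adult leukocytes included abundant cardiomyocyte transcripts such as Ttn (75108 CPM in sham) and Mb (2882 CPM in sham and 274 after MI). Of 3338 genes that were at least 2-fold higher in sham cardiomyocytes than in sham fibroblasts and endothelial cells, 54.6% were called lower, against 22.2% of the 12901 other tested genes (by the same rule 24.8% of 1246 genes high in fibroblasts and 37.3% of 1114 high in endothelial cells), so cardiomyocyte RNA in the sham libraries is a candidate explanation for that part, although sorting on CD45 should remove whole cardiomyocytes. The excess of sham over MI leukocytes, as a share of the cardiomyocyte level, had a 90th to 10th percentile ratio of 8.93 over the 14 cardiomyocyte markers (6.26 to 11.6 in the 4 sham leukocyte libraries, beside 1.25 to 1.69 for the sham cardiomyocyte libraries), which argues against carry-over of 1 fixed profile as the whole cause. Over 3337 of the 3338 genes, those with a listed length, that share rose with gene length (Spearman correlation 0.412 across genes, which are not independent replicates), as carry-over favouring long genes would give. A lower expression of these genes in adult leukocytes after MI was not tested and stays open.

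The higher cell cycle genes in the adult cardiomyocyte fraction after MI might come from other cells in the fraction. Mixed in by their own markers (3.31% of the fibroblast, 4.77% of the leukocyte and 10.8% of the endothelial level), the other populations would bring a median of 68.9% of the observed level over 50 cell cycle genes, with a range of 8.99 to 163%. The leukocyte markers rose by a median of 2.35 and the fibroblast markers had a median of 0.33 and the endothelial markers of -0.34, a spread of 2.69, which argues against a lower share of cardiomyocytes alone. Division of cardiomyocytes themselves was not tested and stays open.

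Among P56 cardiomyocyte libraries, the split that exchanged sham replicate 3 with MI replicate 3 called the most genes. By chi-square per gene MI replicate 3 lay far from its group (283 to 314, against 52.6 to 103 between the others), but sham replicate 3 did not (178 to 219, against 76.0 to 241). Over 452 genes that changed at least 2-fold alike in adult fibroblasts and endothelial cells after MI, MI replicate 3 minus sham replicate 3 had that direction in 88.1%, against 90.9%, 78.3% and 89.2% for the other same-numbered libraries, which argues against an exchange of the 2. Their deviations correlated with listed gene length at -0.213 (sham) and 0.276 (MI), the smaller being 0.213 in size, while the other 6 libraries lay between -0.212 and 0.1995, so a departure that follows gene length cannot be told apart from the usual scatter. A larger infarct or other biological difference in MI replicate 3 was not tested.

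Other splits of the same libraries were counted, 35 per comparison of 2 groups and 100 drawn at random for the rest, with the real split included. For age, 1 of 35 splits, the real one, called as many genes, the lowest possible share. This covers chance between these libraries, not between animals. Counts in cardiomyocytes, fibroblasts, leukocytes and endothelial cells were 10877, 10538, 10890 and 9878, against a highest other of 2, 1, 0 and 1. The same count of 1 of 35 held after MI at P1 in cardiomyocytes (53 against 9), fibroblasts (372 against 14) and leukocytes (7337 against 0), and at P56 in fibroblasts (7868 against 2505), leukocytes (9665 against 459) and endothelial cells (3207 against 786). Chance cannot be excluded this way for MI at P56 in cardiomyocytes (2 of 35; 1498 against 3587) and MI at P1 in endothelial cells (3 of 35; 34 against 265). The split with the most calls exchanged sham and MI replicates 3 in the former and replicates 4 in the latter. Splits that call more genes than the real one point to a structure of the samples that the labelled groups do not follow. An exchange of the endothelial labels was not tested and stays open. For the difference between ages 2 of 100 splits reached the real count in each population (270 against 1152, 4989 against 5978, 7347 against 10102 and 850 against 2668, in the order cardiomyocytes, fibroblasts, leukocytes and endothelial cells), and chance can be excluded. The exceeding split kept both real groupings with 1 age mirrored, so it tested the sum of both responses. For enrichment 1 of 100, the real split itself, reached the real count: 2061 against 1308, 1245 against 0, 976 against 178 and 882 against 48 in the same order.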

How the results depend on the processing

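The settings with edgeR, DESeq2, without libraries over 5% 18S and without 2 libraries whose exchange called the most genes were chosen only after the results were seen. Of 297 gene list tests called with the preset correlation, 1 held with an estimated correlation, the imprinted list with age in fibroblasts. Over all genes named with a test, 385 gene results in 9237 refits kept their direction, and 8946 of these kept their side of the threshold. The other 291 were weaker, 81 of them after MI at P1 in cardiomyocytes and 54 after MI at P1 in endothelial cells. Enrichment counts stayed within 1.5 times their value in every setting run, as did the counts with age other than with the added fold. The cause was not tested for the counts below that moved, unless a setting states it. At this depth genes near the floor of 3 reads are limited most.

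Requiring a fold of at least 2 as well, which by construction calls fewer genes, left 7122 genes with age in cardiomyocytes, 4138 in fibroblasts, 4793 in leukocytes and 3067 in endothelial cells. After MI at P1 it left 177 in fibroblasts, 2433 in leukocytes (960 up and 1473 down) and 8 in endothelial cells, and at P56 996 in cardiomyocytes, 1874 in fibroblasts (1129 up and 745 down), 3623 in leukocytes and 697 in endothelial cells (529 up and 168 down). It left 1933, 3721 and 470 differences between ages in fibroblasts, leukocytes and endothelial cells, and 1049 of 3748 calls alike at both ages, summed over the populations. Over all settings the genes called alike at both ages were 2 to 529 up and 0 to 241 down in cardiomyocytes, 63 to 316 and 2 to 271 in fibroblasts, 329 to 2042 and 628 to 2004 in leukocytes, and 0 to 75 and 0 to 47 in endothelial cells.

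After MI at P1 in cardiomyocytes (53) the count was 16 and 95 with pseudocounts of 0.1 and 1, 168 with no filter, 15 with the filter at 5, 154 with quantile normalization (102 up and 52 down, against 44 and 9). It was 275 with only the compared libraries, 21 with edgeR, 301 with DESeq2 (169 up and 132 down) and 129 without libraries over 5% 18S. In endothelial cells (34) it was 22 and 62 with those pseudocounts, 135 with only the compared libraries, 334 with DESeq2 and 449 without sham and MI replicates 4. In fibroblasts (372) it was 194 with the filter at 5, 626 with DESeq2 and 644 without libraries over 5% 18S (174 up and 470 down, against 313 and 59). After MI at P56 only the compared libraries gave 539 in cardiomyocytes and 1878 in endothelial cells. DESeq2 gave 639 and 1392 differences between ages in cardiomyocytes and endothelial cells.

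Median-of-ratios scaling moved the median of all genes in cardiomyocytes by -0.11 after MI at P56 and by -0.12 in the difference between ages, and quantile normalization by -0.13 in the latter. After MI at P56 the split of 1339 up and 159 down became 1041 and 321 with the former, 761 and 252 with the latter and 1371 and 392 with DESeq2. The differences between ages in cardiomyocytes (270) were 129 with quantile normalization.

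Array weights, which weigh down libraries that depart, gave 4384 genes after MI at P1, 5716 at P56 and 6019 differences in cardiomyocytes, 1384 after MI at P1 and 7588 differences in fibroblasts, and 266 after MI at P1 and 1820 differences in endothelial cells. Leaving out sham and MI replicates 3 of P56 cardiomyocytes gave 4592 genes (2674 up and 1918 down) and 3458 differences; leaving out libraries because of their values can lower the spread by itself.

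Leaving out 1 library gave 2 to 80 genes after MI at P1, 896 to 3679 after MI at P56 and 126 to 2298 differences in cardiomyocytes, 155 to 301 after MI at P1 in fibroblasts, and 0 to 261 after MI at P1 and 452 to 1712 differences in endothelial cells. The lowest and highest came in cardiomyocytes without P1 MI replicate 1 and sham replicate 2, P56 MI replicates 1 and 3, and P1 sham replicate 3 and P56 MI replicate 3. In fibroblasts they came without MI replicates 1 and 2. In endothelial cells the 261 came without sham replicate 4, the 452 without P1 sham replicate 3 and the 1712 without P56 MI replicate 2. The 0 came without MI replicate 1 and without MI replicate 2, with 1488 and 1491 genes at an unadjusted p under 0.05 in limma; on all libraries edgeR called 27 and DESeq2 334.

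Libraries of a population share replicate numbers, and the numbers do not pair them: the deviations of 32 same-numbered sham and MI pairs correlated at -0.426 to 0.360 (median -0.0822), 5 over 0.1, and a library correlated best with its own number in 7. With the replicate block 27 genes were called after MI at P1 and 170 differences in cardiomyocytes and 1 gene after MI at P1 in endothelial cells, and 304 list tests, 296 of them also called without it.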

Other observations

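The tests of a shift toward the neonatal level were chosen only after the results were seen.
After MI at P56, in fibroblasts 8 of 15 hypoxia response genes rose and 1 fell (median 0.47, camera adjusted p 0.0284; adjusted p = 0.536 with an estimated correlation), with the same counts adjusted over the list alone. Among them were the glycolytic Ldha (1.59 ± 0.13) and Pgk1 (1.36 ± 0.17).
In adult leukocytes after MI the immediate early and heat shock genes rose in 8 of 15 (the same adjusted over the list alone; camera adjusted p 0.0199; adjusted p = 0.551 with an estimated correlation). Ier3 (2.19 ± 0.22) and Atf3 (1.75 ± 0.24) led them. Of 15 hypoxia response genes there 8 rose and 4 fell, which did not pass camera (adjusted p 0.451).
In adult endothelial cells after MI 7 of 15 immediate early and heat shock genes rose (12 adjusted over the list alone; Atf3 2.05 ± 0.37, Junb 1.23 ± 0.27; camera adjusted p 2.49e-05; adjusted p = 0.294 with an estimated correlation). There 7 of 17 glycolysis genes rose and 1 fell (10 and 1 adjusted over the list alone; Slc2a1 1.04 ± 0.19; camera adjusted p 0.00879; adjusted p = 0.432 with an estimated correlation).
In the adult cardiomyocyte fraction after MI 11 of 15 immediate early and heat shock genes rose, as many adjusted over the list alone (Atf3 1.84 ± 0.26, Fos 2.50 ± 0.46; camera adjusted p 2.91e-07; adjusted p = 0.159 with an estimated correlation).

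A hypothesis is that after MI adult cells shift toward the neonatal level. The change after MI at P56 was set against the P1 minus P56 difference of the sham libraries across genes, which are not independent replicates, with disjoint pairs of the 4 adult sham libraries in the 2 comparisons. The mean Pearson correlation over 6 assignments was 0.367 in cardiomyocytes (0.260 to 0.464), 0.685 in fibroblasts (0.662 to 0.725), 0.516 in leukocytes (0.445 to 0.574) and 0.574 in endothelial cells (0.557 to 0.588). With the same sham libraries in both comparisons it was 0.423, 0.722, 0.552 and 0.634, beside 0.499 to 0.501 in 100 simulations per population with no effect. The covariance with disjoint pairs was 0.336, 0.637, 0.618 and 0.272, against 0.0360, 0.0197, 0.0232 and 0.0166 for shared libraries with no effect, so the values may reflect a shift in part toward the neonatal level. Cardiomyocyte RNA in the adult sham libraries of the 3 sorted populations would give the same sign and was not separated from it, nor was the isolation, which differed with age. The cardiomyocyte marker medians, as log2(CPM + 0.5) per library, were higher in adult sham than in neonatal sham libraries of fibroblasts (6.04 to 7.00 and 3.93 to 4.59), leukocytes (10.46 to 11.84 and 9.11 to 9.40) and endothelial cells (8.04 to 8.81 and 4.75 to 6.45). In adult MI libraries they were 3.07 to 5.03, 6.59 to 8.80 and 6.54 to 7.64 in that order.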
